A study of Homo sapiens and Mus musculus with 51 samples.

How the data were processed

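Single cells were assayed on a digital microfluidics chip with DIRECT, which reads the DNA methylome and the transcriptome of 1 cell from 1 library. Per the labels' protocols, 5-methyl-dCTP replaced dCTP during reverse transcription and cDNA amplification, and cDNA and genomic DNA then went through bisulfite conversion together. Reads were divided into RNA and DNA by their density of methylated cytosines, per the labels' protocols. The 51 samples were 29 from K562, 6 from HL-60 and 16 from mouse embryonic stem cells (mESC). The K562 samples were 13 DIRECT cells, 3 cells processed in a tube, 2 bulk samples, 3 cells with single-cell bisulfite sequencing (scBS) alone, and 8 cells with RNA sequencing alone. Of those 8 cells, 4 were amplified with normal dNTP and 4 with 5-methyl-dCTP. The mESC samples were 8 cells at day 0 and 8 at day 4.

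For each of 43 samples the authors deposited a table of CpG cytosines. The 27 human tables held the coverage of each (a count of calls) and, per the file headers, the percent of calls that were C or T. The 16 mESC tables were in another form, without that header, and were read as counts of methylated and unmethylated calls. For each of 48 samples the authors deposited a table of read counts per Ensembl gene, without normalization. Per the submitters' processing notes, the tools were Trim Galore 0.6.7, Bismark, SAMtools 1.3.1, methylKit 1.22.0, STAR 2.7.3a, HTSeq 0.12.4, BWA 0.7.17 and DESeq2 1.36.0, with the builds hg19 and mm10. Which tool made which table, and whether counting used strand, is not given in the sources used here. The threshold that divided RNA from DNA reads is not given in the sources used here either.

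For human samples methylated calls were recovered from the deposited percent and coverage, and the largest distance from a whole number in any library was 0.0308 calls. For mESC the counts were used as deposited. The methylation level of a library is its methylated calls as a percent of all its CpG calls, with coverage of 1 or more. Calls on mitochondrial CpGs and other contigs count in this level. Windows, density classes and pairs of cells use autosomes and X only. Mitochondrial CpGs are also given on their own. Levels of groups are means with SD over libraries. Pooled levels carry exact binomial (Clopper-Pearson) intervals at 95% confidence. Windows of 100 kb were compared where both groups had at least 100 pooled calls. Windows were named from those with at least 1000 calls in each group whose difference kept its sign with each cell left out, 3 per direction with the largest difference. CpG-dense windows hold more than 50 CpGs seen per kb and CpG-sparse windows hold 10 or fewer, counted from K562 bulk for human samples and from all mESC libraries for mouse samples. Human windows with no CpG seen in K562 bulk count as CpG-sparse, so that class can hold poorly covered DNA too. For pairs of cells, the same-state share is the percent of shared CpG cytosines at which the majority calls of both cells were the same. Cytosines with tied calls in a cell were left out. The chance share was computed from the share of methylated majority calls of each cell at the shared cytosines.

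Gene counts as deposited were summed over the cells of a group and divided by the summed gene reads to give pooled CPM (read counts scaled to 1e6 per group). Fold changes are log2 ratios of pooled CPM after adding 1 CPM, over genes with pooled CPM of 1 or more in either group. Rows that name no gene stayed out of library sizes, and they took 27.2% of all reads on average (20.9% to 37.3% over 48 libraries). Reads outside genes made up 11.4%, reads on overlapping genes 9.21%, reads placed in several positions 3.93%, unaligned reads 2.43% and low-quality alignments 0.185%. Intervals of pooled CPM and of ratios are exact at 95% (Poisson and binomial). A group with 0 reads on a gene was given a floor of 3 counts over the group, and folds against it are given as "at least", computed without the added CPM. These bounds leave out the counting error of the higher group. Exact 95% lower limits lie below them (for HEMGN in K562 over HL-60, 232 in place of 285). Genes detected per library were compared after thinning every library to the depth of the shallowest one compared (13170 gene reads for DIRECT and tube cells, 4031342 for RNA-only cells), as the exact expected number. Of 57820 human gene IDs, 51996 matched a symbol. The 55401 mouse IDs were not matched to symbols, so the 13 mouse gene lists were not evaluated.

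A cell is not an independent culture and no culture is named for any sample, so each group counts as 1 sample. No test between groups was made and no p-value is given. Groups, comparisons, 22 gene lists and the rule for named genes were fixed before the data were examined. The 9 human lists cover erythroid, megakaryocytic, granulocytic and other blood lineages, cancer-testis genes, DNA methylation enzymes, cell cycle, stress and immediate early genes, and replication-dependent histones. UHRF1 matched no ID under its symbol. A list's median log2 fold was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, as a description of these libraries. Named genes were the 10 per direction with the largest change among genes with pooled CPM of 50 or more and reads in at least 50% of the cells of the higher group, ranked by the smaller of the pooled log2 fold and the log2 fold of the mean CPM over cells. Up to 4 members per list with the highest pooled CPM, and all DNA methylation enzymes, were eligible too.

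Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and R 4.3.3. Alternatives included TMM factors from edgeR 4.0.16, size factors from DESeq2 1.42.0, other pseudocounts and filters, coverage minimums of 2, 3 and 5, other windows, and each library left out in turn. The fold computation was tested on simulated counts with 200 changed genes per comparison, taken from genes above an expression minimum. Simulated cells of a group differed by counting error alone. In the direction with the lower recovery, the sign was recovered for 98% of genes changed 2-fold in the HL-60 and K562 comparison (57820 genes simulated). It was recovered for 100% in the mESC (55401 genes) and dNTP (57820 genes) comparisons. Deposited counts of DIRECT and RNA-only cells varied within groups by more than counting error, so these rates do not cover variation between cells. Within groups, no 2 libraries held identical counts. Gene annotation of hg19 and mm10 was not used here, so methylation at promoters, exons and introns, and the GC content or length of genes, were not analysed here.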

Results

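DNA methylation and gene expression were read from single cells of K562, a chronic myeloid leukemia line, HL-60, a promyelocytic leukemia line, and E14 mouse embryonic stem cells (mESC). Stem cells at day 0 grew on feeder cells with leukemia inhibitory factor (LIF), which holds them undifferentiated. Cells at day 4 had been moved to gelatin without feeders or LIF. Gene reads per sample ranged from 13170 to 368787 in 13 K562 DIRECT cells, from 197576 to 274167 in 3 K562 tube cells and from 13267 to 68901 in 6 HL-60 cells. The 2 K562 bulk samples had 32111 and 46948 gene reads. The 8 K562 cells with RNA sequencing alone had 4031342 to 10168648, and 16 mESC had 41043 to 247376. CpG calls per single cell ranged from 416977 to 4660825 in K562 DIRECT, from 1959162 to 3600026 in tube cells, from 1129571 to 5329515 in scBS cells, from 431993 to 2182506 in HL-60 and from 527325 to 10546673 in mESC. The bulk samples had 19666876 and 18230071 calls. Mean coverage per covered CpG cytosine was 1.60 ± 0.142 in K562 DIRECT cells (SD, n = 13), 1.39 ± 0.0419 in HL-60 cells (n = 6), 1.21 ± 0.0756 in mESC at day 0 (n = 8) and 1.20 ± 0.0155 at day 4 (n = 8). Most sites in single cells thus rest on few calls. Intervals and floors given here cover counting error only, since PCR reads carry no molecular identifiers. Each group counts as 1 sample, so differences are given with the spread over cells and without a test.

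The RNA-only K562 cells ask what 5-methyl-dCTP, the nucleotide that marks cDNA in DIRECT, does to a transcriptome. A set of abundant transcripts was far lower when cDNA was amplified with it. FTH1, the ferritin heavy chain that stores iron, stood at a pooled CPM of 55.4 (53.7 ± 13.7 over 4 cells) against 9837 with normal dNTP, 177-fold lower (95% interval 168 to 188). HBZ, the embryonic zeta globin, had 0 reads against 10379, at least 2395-fold lower. HBA2, an alpha globin, was 951-fold lower (482 to 2203), with 8 reads against 10991. The gamma globin HBG2 went the other way, at a CPM of 29966 against 12163, 2.46-fold higher (2.45 to 2.47).

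The 10 genes furthest below normal dNTP also included SLC25A1, the mitochondrial citrate carrier, with 1 read against 18319, and ADRM1, a ubiquitin receptor of the proteasome, with 1 read against 7429. These 1-read ratios were 12681 (2276 to 500889) and 5142 (923 to 203144). COPE, a coatomer subunit, was 1225-fold lower (478 to 4497), GPX4, which reduces lipid peroxides, 540-fold (284 to 1182, with reads in 1 of 4 cells), and SEPTIN5 703-fold (301 to 2166). ARPC1B, a subunit of the actin-nucleating ARP2/3 complex, was 279-fold lower (179 to 464), and the ribosomal protein gene RPL18 205-fold lower (159 to 269). GATA1, the erythroid transcription factor, was chosen after its values were seen. It stood at a CPM of 23.1 (21.2 to 25.3) with 5-methyl-dCTP and 461 (454 to 469) with normal dNTP. GATA1 had 0 reads in DIRECT, tube and bulk K562 samples, where floors were 1.71, 4.03 and 37.9 CPM. On the higher side stood SLIRP and HNRNPH1, RNA-binding proteins, at 14.1-fold (13.4 to 14.9) and 12.5-fold (12.0 to 12.9). MAGOH, of the exon junction complex, was 11.2-fold higher (10.7 to 11.7), PFDN4, a prefoldin subunit, 13.1-fold (12.3 to 14.1), and COX6C, of cytochrome c oxidase, 9.87-fold (9.46 to 10.3). RPS29 was 12.2-fold higher (11.5 to 13.1), S100A4 28.8-fold (22.8 to 36.9), HBBP1, a globin pseudogene, 31.8-fold (25.7 to 39.9) and GABRG1, read in 2 of 4 normal dNTP cells, 18.7-fold (15.1 to 23.6). ADAMTS4, a protease, was read in only 2 of 4 cells with 5-methyl-dCTP and in 0 of 4 with normal dNTP, at least 586-fold higher, and its log2 fold of 5.84 was 2.08 without 5-methyl-dCTP replicate 3.

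Cell cycle genes were lower with 5-methyl-dCTP as a list. Of 16 members, 12 were lower and 4 higher, with a median log2 fold of -1.24, the 0.24th percentile of random lists. RRM2, a subunit of ribonucleotide reductase, was 5.18-fold lower (4.98 to 5.39) and MCM7, of the replicative helicase, 4.13-fold lower (3.98 to 4.28), while PCNA, the replication clamp, was 2.54-fold higher (2.48 to 2.62). Stress and immediate early genes had 5 of 7 members lower, with a median of -2.03 at percentile 4.39 that was -0.54 without normal dNTP replicate 2. Among them IER2 was 18.3-fold lower (14.6 to 23.3), the chaperone gene DNAJB1 8.49-fold lower (7.26 to 9.99) and EGR1 2.19-fold higher (2.01 to 2.40), a log2 fold of 1.10 that was 0.23 without 5-methyl-dCTP replicate 2. Erythroid genes had 15 of 21 members lower and a median of -0.22, at percentile 51.5, which was -0.35, -0.14 and -1.11 without 5-methyl-dCTP replicates 1, 2 and 4. Replication-dependent histone genes had 5 of 8 members higher, with a median of 0.49 at percentile 85.0. That median was 0.02 and 0.15 without 5-methyl-dCTP replicates 2 and 3, and 1.07, 0.32 and 0.32 without normal dNTP replicates 1, 2 and 3. H4C3 was 4.46-fold higher (4.37 to 4.54), a log2 fold of 2.15 that was 0.86 without 5-methyl-dCTP replicate 2. H2AC6 was 2.26-fold lower (2.15 to 2.37), a log2 fold of -1.17 that was -0.35 without normal dNTP replicate 1. DNA methylation enzymes were divided, 3 higher and 3 lower. DNMT1, the maintenance methyltransferase, was 5.23-fold lower (4.76 to 5.75), and the list's median of -0.07 was 0.16 under TMM and 0.17 under DESeq2 scaling. With 1 library left out it lay between -0.65 (5-methyl-dCTP replicate 1) and 0.29 (5-methyl-dCTP replicate 2), so no direction is given. Cancer-testis genes had 5 of 5 members lower (median -1.71, percentile 13.8, and -2.83 without 5-methyl-dCTP replicate 4), granulocytic genes 4 of 6 (median -1.10, percentile 27.8, and -0.72 without normal dNTP replicate 1) and megakaryocytic genes 2 of 2 (median -1.51, percentile 27.5). CD3D, a T cell gene and the 1 measured member of the other blood lineages, was 17.7-fold higher (11.6 to 28.4).

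Over 12118 genes the pooled profiles of the 2 dNTP groups had a Spearman correlation of 0.749. This is a correlation across genes, as are those that follow, and genes are not independent replicates. Single libraries were compared over 17241 genes with a mean CPM of 1 or more over all human libraries. They correlated at 0.877 ± 0.00841 within normal dNTP (6 pairs), 0.778 ± 0.0309 within 5-methyl-dCTP (6 pairs) and 0.752 ± 0.0353 between them (16 pairs). Over 8753 genes with a mean CPM of 10 or more these values were 0.870 ± 0.0138, 0.789 ± 0.0340 and 0.677 ± 0.0331. At 4031342 reads, 11769 ± 1896 genes were detected with 5-methyl-dCTP and 11636 ± 528 with normal dNTP (SD, n = 4 each), a difference within the spread over cells. It turned to -803 without 5-methyl-dCTP replicate 1 and reached 576 without 5-methyl-dCTP replicate 4. It turned to -94.7 without normal dNTP replicate 2 and to -78.2 without thinning. For genes with at least 5 reads it turned to -1451 (8307 ± 1063 against 9757 ± 351), which is beyond the larger SD of that setting. Fewer genes were also detected with 5-methyl-dCTP when these libraries were thinned to the depth used for DIRECT and tube cells. There 3070 ± 136 genes were detected with 5-methyl-dCTP (2882 to 3207) and 3903 ± 274 with normal dNTP (3666 to 4288). These ranges did not overlap. The median log2 fold of all measured genes was -0.54, and TMM scaling moved it by 0.21, DESeq2 size factors by 0.22, a pseudocount of 5 CPM by 0.20 and medians over cells by 0.12. Counts of HBA2, HBG2, FTH1, RPS29, RPL18 and HBBP1 are uncertain because near-identical genes or pseudogenes share their reads, and those of genes overlapping another are uncertain because strand was not stated.

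The tube and bulk K562 samples ask whether the chip changes what DIRECT reads. Transcripts of the mitochondrial genome, which encode subunits of the respiratory chain, took a larger share of gene reads in tube cells than in DIRECT cells. Mitochondrially encoded genes took 13.6% ± 3.99 of gene reads in DIRECT cells (SD, n = 13) against 21.6% ± 2.90 in tube cells (n = 3) and 15.5% ± 0.589 in bulk (n = 2). At 13170 reads, DIRECT cells had 3703 ± 764 genes detected and tube cells 2976 ± 346, a difference of 727 that is smaller than the spread over DIRECT cells. It turned to -33.8 without thinning and to -18.8 for genes with at least 5 reads. K562 DIRECT replicate 10 had the most genes, 18798 before thinning and 5438 after. The pooled DIRECT profile correlated at 0.736 with the tube profile (18691 genes), 0.735 with the 5-methyl-dCTP profile (18419 genes), 0.682 with the normal dNTP profile (18719 genes) and 0.675 with bulk (18420 genes). With HL-60 DIRECT cells, another cell line, it was 0.678 (19176 genes), so the pooled values for normal dNTP and bulk do not set K562 apart. Between single libraries, over the same 17241 genes, DIRECT cells correlated at 0.501 ± 0.0625 with bulk, 0.516 ± 0.0962 with normal dNTP and 0.399 ± 0.0594 with HL-60. There the K562 libraries stood higher. At a mean CPM of 10 or more these were 0.445 ± 0.0640, 0.400 ± 0.102 and 0.310 ± 0.0609, with normal dNTP within its spread of HL-60. HL-60 cells correlated with each other at only 0.419 ± 0.0568 over the 17241 genes. Their gene reads were far below those of normal dNTP cells, so depth and cell line cannot be told apart in that comparison. Gene reads of the bulk samples lay within the range of HL-60 cells, but each bulk sample is not a single cell. Bulk samples held 79059 gene reads together, which limits the value for bulk.

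The methylome of K562 DIRECT cells was compared with that of K562 cells processed in a tube, with scBS alone and in bulk. CpG methylation in DIRECT cells was 43.3% ± 1.95 (SD, n = 13), lower than in the 2 bulk samples (48.6% ± 0.0706) by more than the spread over cells. In scBS cells it was 45.5% ± 0.867 (n = 3), and the difference of -2.19 percentage points from DIRECT barely passed 1 SD of the DIRECT cells (1.95). In tube cells it was 45.3% ± 4.42 (n = 3), a difference of -2.07 that lies within their spread. Along the genome, over 27196 windows of 100 kb, pooled DIRECT levels and the levels of both bulk samples pooled had a Pearson correlation of 0.977. Without bulk replicate 2 this value was 0.970. The 2 bulk samples, each taken alone, correlated with each other at 0.972 over 24007 windows. Pooled tube and bulk levels correlated at 0.954 (18961 windows) and scBS and bulk levels at 0.904 (18940 windows). These pools held 7706666 tube and 10463352 scBS calls against 29682672 in DIRECT, so the pooled correlations differ in depth too. Single DIRECT cells correlated with bulk at 0.841 ± 0.0807 (0.651 to 0.918), single tube cells at 0.907 ± 0.0195 and single scBS cells at 0.817 ± 0.0803.

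With classes from CpGs seen in K562 bulk, CpG-dense DNA, which includes CpG islands, was less methylated than CpG-sparse DNA in every K562 group. In DIRECT cells CpG-dense windows stood at 24.1% ± 2.73 and CpG-sparse windows at 39.2% ± 2.41, and windows of middle density at 53.4% ± 2.04 (n = 13). CpG-dense windows stood at 31.4% ± 1.12 in scBS cells, 29.0% ± 0.836 in bulk and 26.3% ± 5.03 in tube cells, while CpG-sparse windows stood at 38.9% ± 1.45, 43.0% ± 0.608 and 39.6% ± 4.03. Dense minus sparse was -15.1 in DIRECT cells, -13.3 in tube cells, -14.0 in bulk and -7.48 in scBS cells. When CpGs seen in any human library defined the classes, the value in scBS cells moved to -1.23, in tube cells to -8.30 and the others by less than 1.5 times. In scBS replicate 1 CpG-dense windows then stood above CpG-sparse ones, at 34.9% against 33.6%, so the order is not secure for scBS.

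The distance of DIRECT from scBS and from bulk depended on which CpGs were used. DIRECT minus scBS was -2.19 points over all calls, -4.03 with coverage of at least 2, -8.07 with 3 and -14.9 with 5. It was -0.667 as a mean over CpG sites, -0.542 over common 100-kb windows and -0.179 over windows with 100 pooled calls. DIRECT minus bulk was -5.37 points over all calls, -10.05 with coverage of at least 3 and -14.8 with 5. Over common windows it was -1.77, which is under the spread over DIRECT cells, and over windows with 100 pooled calls it was -2.63. DIRECT minus tube was -1.30 with coverage of at least 5 and -2.91 over common windows, both within its spread. The tube mean rests on replicate 3, at 50.4% (95% interval 50.4 to 50.5) beside 42.5% and 43.1%. In windows unmethylated in bulk replicate 1 it stood at 8.17%, against 3.25% and 3.36% in the 2 other tube cells and 2.74% to 5.38% in DIRECT cells. DIRECT minus tube was 0.476 without tube replicate 3, -3.50 without replicate 1, -3.18 without replicate 2 and 0.0622 between medians.

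**Figure D1:**
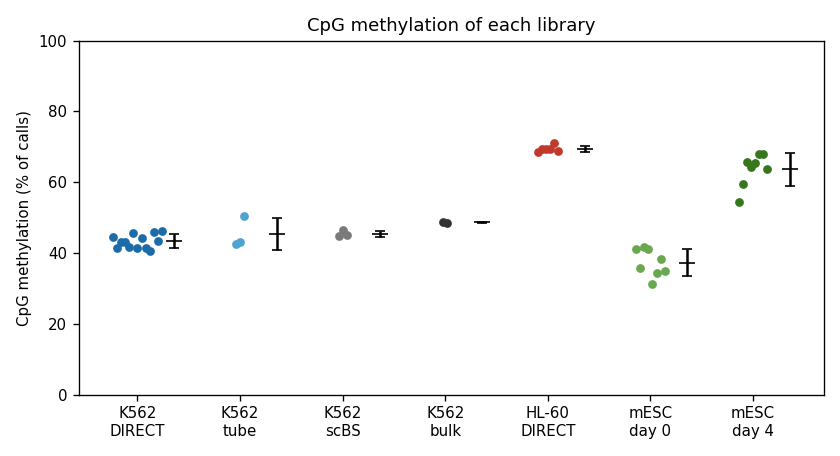
CpG methylation of each library as a percent of all its CpG calls, with the mean and SD of each group beside its points (1 point per cell or bulk sample). The 6 HL-60 cells sit between 68.6% and 71.1%, above all 13 K562 DIRECT cells (40.4% to 46.1%), and all 8 day 4 mESC (54.3% to 68.0%) sit above all 8 day 0 mESC (31.2% to 41.8%).

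**Figure D2:**
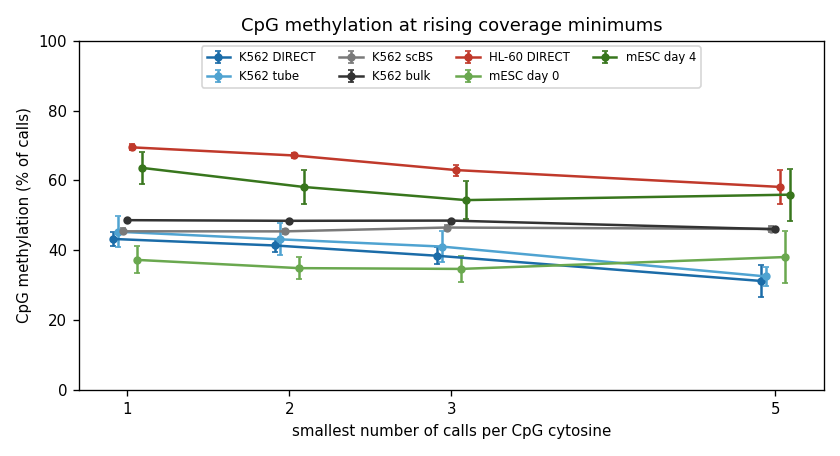
Mean CpG methylation (percent of calls, with SD over libraries) when only CpG cytosines with at least 1, 2, 3 or 5 calls are used. In K562 DIRECT the mean was 43.3% at 1 call and 31.3% at 5, while in scBS it was 45.5% and 46.1%.

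HL-60 was compared with K562 to ask whether the joint assay separates blood cell lines by both layers. HL-60 cells carried a granulocytic program and K562 cells an erythroid one. MPO, the peroxidase of neutrophil granules, had a pooled CPM of 2963 (2910 ± 540 over 6 cells) in HL-60 and was read in 6 of 6 cells. In K562 it had 2 reads over 13 cells, a ratio of 2598 (95% interval 717 to 21489). HEMGN, an erythroid nuclear protein, had a CPM of 3097 in K562, with reads in 13 of 13 cells, and 0 reads in HL-60, at least 285-fold lower. RHAG, of the red cell membrane, was 80.02-fold lower in HL-60 (27.3 to 388), on 3 reads.

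Of 21 granulocytic and myeloid genes measured, 17 were higher in HL-60, with a median log2 fold of 2.71, above all 10000 random lists. MS4A3, of granulocyte and monocyte progenitors, was 6.57-fold higher (5.44 to 7.94), with reads in 4 of 13 K562 cells and a log2 fold that went from 2.71 to 4.26 without K562 replicate 13. LCP1 and SERPINB1 lay within their counting intervals of equal, at ratios of K562 to HL-60 of 1.02 (0.843 to 1.25) and 1.222 (0.723 to 2.20). SERPINB1 was read in 3 of 6 HL-60 cells, and its log2 fold went from -0.28 to -2.83 without HL-60 replicate 3. Of 20 erythroid genes measured, 17 were lower, with a median of -2.67, below all 10000 random lists. With unread genes at their bound this median was -1.77. The gamma globins HBG2 and HBG1, which share reads, were 24.8-fold (14.8 to 45.4) and 17.9-fold (10.8 to 32.1) lower. The granulocytic median was 1.77 without HL-60 replicate 5, 1.90 without replicate 3 and 2.01 without replicate 6, and the erythroid median was -3.35 without HL-60 replicate 4.

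**Figure D3:**
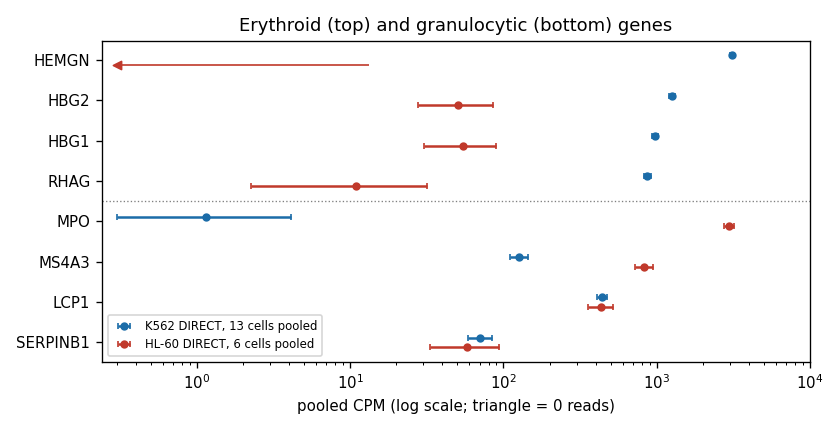
Pooled CPM on a log axis, with exact 95% Poisson intervals, of the 4 erythroid and 4 granulocytic genes with the highest pooled CPM (K562 DIRECT, 13 cells; HL-60, 6 cells; a triangle marks 0 reads, its line running up to the upper limit). The erythroid genes are lower in HL-60, MPO and MS4A3 are higher, and LCP1 and SERPINB1 overlap, with signs that turn for LCP1 under scalings and for both with single cells left out.

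Among the 10 genes furthest above K562 in HL-60 were RNASE2, a secreted granule ribonuclease, at least 224-fold higher, SRGN, the granule proteoglycan serglycin, 117-fold (90.3 to 155), and PTPN7, a phosphatase of blood cells, at least 106-fold. SOX4, a transcription factor, was at least 69.8-fold higher, IRAK3, which restrains Toll-like receptor signals, 209-fold (55.7 to 1765, on 2 K562 reads), and GAPT, read in 3 of 6 HL-60 cells, 431-fold (74.9 to 17288, on 1 K562 read). ENSG00000263264 was 365-fold higher (98.7 to 3048, on 2 K562 reads) and ENSG00000229645, read in 3 of 6 HL-60 cells, at least 144-fold. ZNF155 was 218-fold higher (72.5 to 1074, on 3 K562 reads), but its mean over HL-60 cells was 461 ± 1074 CPM and its log2 fold of 7.11 was 2.32 without HL-60 replicate 6. On the other side, the long non-coding RNAs LINC00958 and UCA1 were at least 52.0-fold and 31.3-fold lower in HL-60. CPEB4, which regulates translation, was at least 48.2-fold lower, the water and glycerol channel AQP3 at least 22.7-fold, CSAG1 at least 21.5-fold, GALNT5, of O-glycosylation, at least 21.3-fold and GMPR at least 16.9-fold. EMSY-DT and MAGEC2, a cancer-testis gene, were at least 14.4-fold and 12.7-fold lower.

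Both measured members of the cancer-testis list were lower in HL-60 (median -4.94, below all random lists), with PRAME 30.7-fold lower (20.8 to 47.5) and MAGEC1 35.1-fold lower (9.67 to 291, on 2 reads). All 8 replication-dependent histone genes were lower (median -3.09, below all random lists). H1-2 was 16.4-fold lower (10.7 to 26.5), H2BC12 13.5-fold (8.17 to 24.2), H2AC6 27.5-fold (11.7 to 84.8) and H4C3 2.71-fold (2.13 to 3.50). Cell cycle genes were nearer to even, with 7 of 16 higher and a median of -0.38 at percentile 20.6, which was -0.13 without HL-60 replicate 1 and -0.15 without K562 replicate 7. Of 6 DNA methylation enzymes, 4 were lower, with a median of -0.96 at percentile 9.15. DNMT3B, a de novo methyltransferase, was 21.3-fold lower (3.75 to 847, on 1 read in replicate 1), TET1 3.82-fold lower (1.90 to 8.98) and DNMT3A 2.76-fold lower (1.03 to 10.4), while TET3 was 2.701-fold higher (1.84 to 3.90), a log2 fold of 1.42 that was 0.85 without HL-60 replicate 5. Stress and immediate early genes had 6 of 7 members lower (median -1.26, percentile 14.9), among them EGR1, 8.91-fold (5.28 to 16.4), a log2 fold of -3.13 that was -6.44 without HL-60 replicate 6. Megakaryocytic genes had 6 of 9 lower and a median of -1.10 at percentile 18.9, which was 0 with unread genes at their bound and 1.25 over members with CPM of 10 or more, and FLI1, a transcription factor of that lineage, was 6.34-fold higher (3.11 to 12.9). Of 4 genes of other blood lineages, 2 were higher (median 0.01, percentile 62.4), on 1 HL-60 read each, and the median was -1.10 without HL-60 replicate 1 and -0.87 without replicate 3. The median of all 19176 genes was -0.23, and TMM moved it by -0.31, DESeq2 by -0.32, leaving out mitochondrially encoded genes by 0.17, and medians over cells or thinning by 0.23. Mitochondrially encoded genes took 20.3% ± 7.47 of gene reads in HL-60 and 13.6% ± 3.99 in K562.

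The HL-60 methylome stood far above that of K562, at 69.5% ± 0.863 (SD, n = 6) against 43.3% ± 1.95 (n = 13). The difference of 26.2 points exceeded the larger SD over cells (1.95). It lay in CpG-sparse DNA, at 73.0% ± 1.45 against 39.2% ± 2.41, and in DNA of middle density, at 75.0% ± 0.865 against 53.4% ± 2.04. CpG-dense DNA was alike, at 23.8% ± 2.53 against 24.1% ± 2.73. Of 21532 windows of 100 kb, 90.5% were more methylated in HL-60, with a median difference of 32.9 points. The X chromosome stood at 70.4% ± 1.86 in HL-60 and 33.9% ± 2.72 in K562.

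With 1000 calls or more in both lines, 58 windows remained, and 41 of them were higher in HL-60. Chromosome 18 from 13400001 to 13500000 (hg19) stood at 86.2% (95% interval 83.97 to 88.3) against 9.78% (8.70 to 10.9). Chromosome 16 from 46300001 to 46400000 stood at 76.2% (74.5 to 77.9) against 6.24% (5.84 to 6.65), and the next window, from 46400001 to 46500000, at 75.8% (74.1 to 77.4) against 7.69% (7.33 to 8.07). These chromosome 16 windows held 14109 and 20063 K562 calls, far above the minimum of 1000, and 2415 and 2645 HL-60 calls. Only 58 of the 21532 windows with 100 calls reached that minimum, so they are unusual. Why calls gathered there was not tested. Lower in HL-60 were chromosome 7 from 4700001 to 4800000 (38.8% against 70.7%), chromosome 6 from 74100001 to 74200000 (61.1% against 75.5%) and chromosome 19 from 11000001 to 11100000 (54.6% against 68.2%). In these 3 windows the SD over HL-60 cells was 32.4, 21.1 and 21.4 points, so all 3 differences, at -31.8, -14.4 and -13.6 points, lie within the spread over HL-60 cells. The HL-60 profile correlated with K562 bulk at 0.433 over 21539 windows.

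The stem cells ask how methylation and expression differ once LIF and feeders are withdrawn. Day, LIF, feeders and substrate differ together between the groups. CpG methylation was 63.6% ± 4.61 at day 4 and 37.3% ± 3.86 at day 0 (SD, n = 8 each), and all day 4 cells stood above all day 0 cells. CpG-sparse DNA held 75.7% ± 5.55 at day 4 against 44.0% ± 5.60 at day 0, and DNA of middle density 68.9% ± 4.29 against 42.0% ± 4.01. CpG-dense DNA was low on both days, at 6.55% ± 0.666 and 4.98% ± 2.11.

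The higher level at day 4 covered nearly the whole genome: 99.96% of 25227 windows of 100 kb were higher at day 4, with a median difference of 27.6 points and 5th and 95th percentiles of 15.3 and 39.6. Chromosome 7 from 133000001 to 133100000 (mm10) stood at 78.7% (76.7 to 80.6) against 25.9% (24.3 to 27.6). Chromosome 12 from 102600001 to 102700000 stood at 81.2% (79.6 to 82.6) against 29.3% (27.8 to 30.8), and chromosome 8 from 122900001 to 123000000 at 81.0% (78.7 to 83.3) against 31.7% (29.5 to 34.0). Of 8983 windows with 1000 calls, 1 was lower at day 4, and none was lower with each cell left out in turn. Window levels correlated at 0.809 between the days. Over CpGs with at least 5 calls the difference between the days was 17.8 points in place of 26.3.

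In expression, the pooled profiles of day 4 and day 0 correlated at 0.793 over 20148 genes, and the median log2 fold was -0.10, which no scaling moved by more than 0.1. ENSMUSG00000095936 was at least 27.0-fold higher at day 4 and ENSMUSG00000070890 at least 23.3-fold higher, each with 0 reads at day 0. ENSMUSG00000029028 was lower at day 4, with 1 read against 358 (a ratio of 226, 40.2 to 8936), and ENSMUSG00000079177 had 0 reads against 110, at least 23.1-fold lower. At 41043 reads, 7001 ± 567 genes were detected at day 4 and 7359 ± 1127 at day 0.

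Pairs of cells were compared to see which layer tells the groups apart. By CpG state, 2 K562 DIRECT cells gave the same call at 83.1% ± 0.489 of shared CpGs (78 pairs), 2 HL-60 cells at 84.1% ± 0.367 (15 pairs) and a K562 with an HL-60 cell at 61.3% ± 2.11 (78 pairs). Chance shares for these pairs were 50.9%, 58.7% and 47.2%, so they lay 32.2, 25.4 and 14.1 points above chance. Between mESC the share was 69.0% ± 1.63 within day 0 (28 pairs), 76.0% ± 2.48 within day 4 (28 pairs) and 63.9% ± 3.18 between days (64 pairs). The chance share was 55.2%, 51.9% and 47.6%, so pairs within day 0 lay 13.8 points above chance and pairs between days 16.4. With coverage of at least 3, the distance of pairs within K562 from pairs with HL-60 was 44.9 points in place of 21.7, and that of pairs within day 0 from pairs between days 0.106 in place of 5.06.

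The cell most alike in CpG state belonged to the same group for 13 of 13 K562, 6 of 6 HL-60, 8 of 8 day 0 and 8 of 8 day 4 cells. When cells were ranked by the share less the chance share, this held for 0 of 8 day 0 cells and for all cells of the other groups. The top cell of each day 0 cell was then a day 4 cell. By expression, the most alike cell belonged to the same group for 13 of 13 K562, 1 of 6 HL-60, 8 of 8 day 0 and 4 of 8 day 4 cells. Expression of single cells correlated at 0.503 ± 0.0808 within K562 DIRECT, 0.419 ± 0.0568 within HL-60 and 0.399 ± 0.0594 between them, at gene reads that differed between the lines.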

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

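None of the comparisons of single libraries in this part was chosen after its result was seen, and no explanation was tested for the values. In each group of 4 to 10 samples, the distance of the highest and lowest sample to its neighbour was set against the range of the group; 47 such sets were compared and 4 samples stood apart, where chance gives about 2.35, 1 in 20. HL-60 replicate 2 had 5997 genes detected after thinning, against 3071 to 3815 in the other 5 cells; it also had the fewest gene reads of the HL-60 cells (13267) and the highest share of reads outside genes (25.3%, 95% interval 24.7 to 25.9). HL-60 replicate 5 had CpG methylation of 71.1% (71.0 to 71.2), against 68.6% to 69.4% in the others. Mitochondrial CpGs of mESC day 0 replicate 5 were called methylated at 19.5%, against 2.32% to 4.64% in the other 7 cells. Mitochondrial CpGs of mESC day 4 replicate 3 stood at 3.15%, against 1.66% to 2.06%.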

How the results depend on the processing

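The windows with 100 pooled calls in both groups, the density classes from all human libraries and the removal of doubted libraries together were chosen after the data were seen. For the 23 values that answer a comparison, leaving out 1 library gave 222 values within 1 spread of the value reported and 3 beyond it, and other settings gave 94 and 27. For the 16 other list medians these were 200 and 5, and 131 and 11, with 1 reversed. For 127 single genes they were 1766 and 4, and 940 and 56. With a coverage minimum of 3 and of 5, DIRECT minus scBS moved to -8.07 and -14.9 points, DIRECT minus bulk to -10.05 and -14.8, and mESC day 4 minus day 0 to 19.7 and 17.8. With a minimum of 3, dense minus sparse moved to -19.4 in DIRECT, -17.6 in tube, -18.8 in bulk and -52.7 in HL-60, and the distance within minus between groups of cell pairs to 44.9 for K562 and 0.106 for mESC. Over common 100-kb windows DIRECT minus bulk moved to -1.77 and HL-60 minus K562 to 22.8; over windows with 100 pooled calls DIRECT minus scBS, DIRECT minus bulk and HL-60 minus K562 moved to -0.179, -2.63 and 32.4. Classes from all human libraries moved dense minus sparse to -10.2 in DIRECT, -8.30 in tube, -10.1 in bulk, -1.23 in scBS and -44.1 in HL-60, and classes of over 70 and of 5 or fewer CpGs moved it to -52.3 in HL-60. The correlation of the dNTP profiles moved to 0.789 without a filter and to 0.618 at CPM of 10 or more. The erythroid median moved to -3.67 with a pseudocount of 0.1, the granulocytic one to 2.01 with 5, and the megakaryocytic one turned to 1.25 over members with CPM of 10 or more, which drops the thinly read members. For the other moves the cause was not tested. With each replicate left out in turn, the granulocytic median ranged from 1.77 to 2.90 and DIRECT minus tube from -3.50 to 0.476. Without the doubted libraries (K562 DIRECT replicate 10, tube replicate 3, mESC day 0 replicate 5 and day 4 replicate 1) DIRECT minus tube was 0.711, and the mESC difference 26.8. No paired analysis was possible between groups because replicate numbers only name cells and no result comes from a test. Methylation and expression of a DIRECT cell are paired, but these layers were not compared within cells here. Alternatives for promoters, exons and introns, and for mouse genes without mitochondrially encoded ones, were not run. Depth limits single genes: the floor of an HL-60 cell averaged 87.1 CPM and that of a K562 DIRECT cell 57.4.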

Other observations

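Tests chosen only after the result was seen were the comparison of call density along the genome, the tests of covered sites, the test of conversion against scBS, and the tests of genomic DNA and of HL-60 reads in K562 DIRECT replicate 10.

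The density of CpG calls in 1-Mb windows, set against windows of like CpG content, differed between HL-60 and K562 in long segments. HL-60 had more calls on chromosome 8 from 126000001 to 129000000, with a mean log2 ratio of 1.63. It also had more on chromosome 18 from 49000001 to 60000000 (1.296) and from 64000001 to 76000000 (1.32), and on chromosome 6 from 128000001 to 135000000 (1.15). K562 had more calls on chromosome 22 from 19000001 to 24000000 (-2.28), chromosome 13 from 90000001 to 94000000 (-2.02), chromosome 16 from 87000001 to 91000000 (-1.99) and chromosome 5 from 89000001 to 93000000 (-1.49). In each of these segments all 6 HL-60 and all 13 K562 DIRECT cells had the same direction, and the log2 ratio to K562 DIRECT was between -0.0996 and 0.128 in K562 bulk and between -0.119 and 0.199 in K562 tube cells. In K562 scBS cells that ratio was between -0.547 (chromosome 13) and 0.169, with -0.310 on chromosome 16. As background, HL-60 carries amplified MYC, a gene of chromosome 8, and K562 carries amplified copies of the BCR-ABL1 fusion, with BCR on chromosome 22.

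Chromosomes of K562 differed in methylation more than those of HL-60 did. In K562 DIRECT cells chromosome 19 stood at 54.6% ± 1.73 and chromosome 17 at 53.2% ± 1.96, while chromosome 8 stood at 36.3% ± 2.497 and X at 33.9% ± 2.72 (SD, n = 13). In HL-60 the same chromosomes stood at 70.02% ± 0.682, 73.0% ± 1.496, 69.9% ± 0.638 and 70.4% ± 1.86 (n = 6). In mESC, chromosome 17 was the lowest on both days, at 33.3% ± 4.03 and 57.4% ± 5.91 (n = 8 each). Mitochondrial CpGs were called methylated at 2.03% ± 0.554 in K562 DIRECT cells, 2.91% ± 0.266 in tube cells, 2.47% ± 0.00289 in bulk and 12.1% ± 4.25 in scBS cells.

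CpG methylation in K562 DIRECT cells lay below bulk and scBS. In windows that were unmethylated in bulk replicate 1, DIRECT cells lay 0.463 points above bulk replicate 2. More complete conversion of unmethylated cytosines in DIRECT was thus not seen there. The test cannot decide for the whole difference, since bulk replicate 2 stood at 3.31% there, too low to show -5.37 points. Nor do such windows show how methylated cytosines were converted. At mitochondrial CpGs DIRECT cells stood at 2.03% ± 0.554 and bulk at 2.47%, within the SD over DIRECT cells. Conversion stays open against scBS too, from which DIRECT differed by -0.479 points in those windows (within an SD of 0.694). At mitochondrial CpGs DIRECT differed from scBS by -10.1 points (beyond an SD of 4.25). The choice of covered sites stays open for bulk, with -2.63 points over windows with 100 pooled calls but -1.77, within 1 SD, over common windows, and for scBS, with -0.179 and -0.542 points. Also open is that methylated reads of CpG-dense DNA may have been assigned to RNA: the log2 ratio of calls in methylated to unmethylated windows, CpG-dense less CpG-sparse, was lower in DIRECT than in scBS by a difference of -0.659, with an SD of 0.297 over DIRECT cells. No biological explanation was tested, since all groups are K562.

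Many transcripts lay far lower with 5-methyl-dCTP, and a candidate explanation is that amplification with 5-methyl-dCTP loses many of them in each kind of library made with it. To keep the controls apart, 446 genes at least 8-fold lower were chosen against normal dNTP replicates 1 and 2, and DIRECT was set against replicates 3 and 4. Their median log2 fold in K562 DIRECT was -2.81, below all random lists (95% of them between -0.64 and -0.24), and it was -5.20 in tube cells and -3.38 in bulk, which is in line with such a loss. The loss did not extend to each gene, since 421 of the 446 were below 0 in DIRECT and HBA2, at 0.370 CPM with 5-methyl-dCTP, stood at 204 in DIRECT against 351 with normal dNTP, though it had 1 read in tube cells and 0 in bulk. GC content and length were not tested, and differences in depth and in handling between the RNA-only and joint libraries remain open as untested.

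K562 DIRECT replicate 10 had the most genes detected, and read depth is argued against, since at equal depth it still had 5438 genes against 2727 to 4574 in the 12 other cells. Reads from an HL-60 cell are argued against as the whole cause: 10 genes furthest above the 12 other K562 cells in HL-60 reached 2.63% of their HL-60 level, with 40 of 50 reads on AFF3 (named after its values were seen) and 0 on MPO. At the upper counting limit, against the HL-60 cell with the lowest level, this is 685 of 13170 reads for 864 genes beyond the highest other cell, so a smaller part stays open. What stays open is that genomic DNA reads may have been counted as gene reads: 1.98% of its gene reads lay on genes unread in all RNA-only cells (0.258% to 1.55% in the others) and 22.8% of its reads lay outside genes (8.86% to 20.6%). No biological explanation was tested.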
